A study of Mus musculus with 5 samples.

How the data were processed

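Cells of the embryonic cortex of wild-type CD1 mice were profiled by Drop-seq, which captures single cells with barcoded beads in droplets and counts RNA molecules by unique molecular identifiers (UMIs). Embryos were taken at E11.5, then at E13.5 and E15.5, and last at E17.5, and per the labels' protocols every library but E11.5 was sorted for viable cells. The labels name 5 libraries, of which 2 are batches of E15.5 whose cells share a table and carry no batch name. The table holds stretches of columns 1 to 3000 and 3001 to 5000, with depth falling along each. It was used as 1 library, and as 2 in an alternative. The deposited tables hold raw UMI count values per gene and cell, 8 tables in all, with 1 of all cells and 1 of the cells the authors kept as cortical for each age. Per the submitters' processing notes reads were aligned to mm10, and the aligner, the annotation and the counting tool are not given in the sources used here. The count of each cell in the authors' cortical table was identical to that in the all-cell table. Every column was used apart from cells under 500 UMIs.

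All-cell tables held 2000 cells and 5502525 UMIs at E11.5, 2000 and 4691881 at E13.5, 5000 and 13211734 at E15.5, and 2000 and 3877979 at E17.5. Cortical tables held 1418, 1137, 2955 and 880 cells, with median UMIs per cell of 2150.5, 2277, 2583 and 1929.5. Cells under 500 UMIs were left out (6, 98, 9 and 1 of the all-cell tables). In total 21201 genes were listed in at least 1 age and 14720 in all, and a gene not listed at an age was given a count of 0 there.

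Each age was clustered on its own from the all-cell table with scanpy 1.11.5 (python 3.11.15, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3). Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes without hemoglobin and mitochondrial genes, 30 principal components, 15 neighbours and Leiden resolution 1 were used with a fixed seed. Clusters were named from 15 panels of marker genes by the mean log2 fold of a panel's markers against the equal-weight mean of the age's clusters, with at least 3 markers up by 0.5 and a mean of at least 0.5. That reference and the smallest mean were settled after the names were seen, and clusters below it stayed unnamed. Under a reference common to all ages the E11.5 neurons would have been named diencephalic. A class was compared only if none of its clusters had more markers of another class than of its own among its 10 leading genes. The check was changed after it was seen to fail: against the naming reference, clusters of excitatory neurons at E11.5 (152 cortical cells) and at E15.5 (492) failed it, and with the fold against all other cells of the age every cluster of the 3 classes passed. With the cortical tables clustered alone, 3 of 4 clusters of E11.5 radial precursors (458 of 709 cells) and 1 of 4 of E17.5 excitatory neurons (101 of 519) failed it and were kept. Scrublet called 18 of 10886 cells (0.165%) as doublets, too few to be relied on, so doublets were kept and their removal was an alternative.

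UMIs of the cortical-table cells of a class were summed per age, giving 4 libraries. A linear trend with embryonic day was tested with edgeR 4.0.16 (R 4.3.3) by quasi-likelihood F tests with TMM scaling, on genes with at least 10 UMIs in at least 2 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors were the slope divided by the root of F. Gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2, for lists of at least 5 measured members, with a preset correlation of 0.01 and with an estimated one. Counts within the list were adjusted over the list alone, and the 3 or 4 hemoglobin genes were counted only. The 23 lists are those named with their counts in the text. The test, the classes, the marker panels, the lists and the rule for named genes were chosen before the data were examined. By that rule the text names the 12 steepest rises and 12 steepest falls of at least 50 CPM past the test, without predicted, hemoglobin and marker genes, and up to 4 members of each list by smallest p. Results for some genes are not reported here. Where fewer passed, genes with the largest ratio between E17.5 and E11.5 by the bound of its counting interval filled in, as values only.

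The trend test was run on straight slopes of 200 genes simulated at the depth and dispersion of each class. Recovery at 0.3, 0.6 and 1 log2 per day was 38.1%, 96.7% and 100% in radial precursors (6 of 9075 unchanged genes called). In intermediate progenitors it was 28.8%, 94.0% and 100% (1 of 7599) and in excitatory neurons 41.8%, 92.5% and 100% (5 of 9984). Departure from a line was not simulated, so 0 calls in excitatory neurons do not show that steep changes are absent. Shares of cells carry exact Clopper-Pearson 95% intervals, and levels in CPM, UMI counts scaled to a common library total, exact Poisson intervals. Cells counted as carrying cell-cycle transcripts had at least 2 list UMIs after thinning to 1000 UMIs, with shallower cells left out. Similarity was Pearson r on log2 CPM plus 10, over genes of at least 50 CPM, with sums thinned to the shallowest library.

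Alternatives were DESeq2 1.42.0 size factors and its Wald test, no low-count filter, a filter of 30 UMIs, leaving out each library, sums thinned to the shallowest library, cells of the all-cell tables, Leiden resolutions of 0.5 and 2, other cell-cycle thresholds and other similarity thresholds. Further ones were added after the data were seen and are named with their values in the closing section. Figures were drawn with matplotlib 3.10.9.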

Results

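Radial precursors made up a smaller share of the cortical cells at E13.5 and later than at E11.5, and excitatory neurons a larger one. Radial precursors, the dividing cells that line the ventricle and from which adult neural stem cells descend, were 61.3% (58.7 to 63.9%, 867 of 1414 cells) at E11.5 and 18.4% (16.2 to 20.8%, 207 of 1125 cells) at E13.5. They were 9.31% (8.28 to 10.4%, 275 of 2955 cells) at E15.5 and 8.18% (6.46 to 10.2%, 72 of 880 cells) at E17.5, with exact Clopper-Pearson 95% intervals in brackets. Intermediate progenitors, which divide a limited number of times and then give rise to neurons, were 9.97%, 15.9%, 14.6% and 25.5%. Excitatory neurons were 23.8%, 42.7%, 54.1% and 58.0%. Cells in clusters without a name were 4.03%, 22.5%, 19.8% and 4.89%. Cycling cells of the cortical tables at E15.5 included 46 and 15 cells in clusters that carried the name of ganglionic eminence precursors, and these were not counted in any of the 3 classes. With other clustering the E11.5 share of radial precursors was between 33.9% and 65.4%. For intermediate progenitors it was up to 33.2% at E15.5 and down to 12.2% at E17.5, so the order of these ages also depended on the clustering. The intervals here and elsewhere cover counting error only, as each age had 1 library, and no test compared shares between ages.

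**Figure D1:**
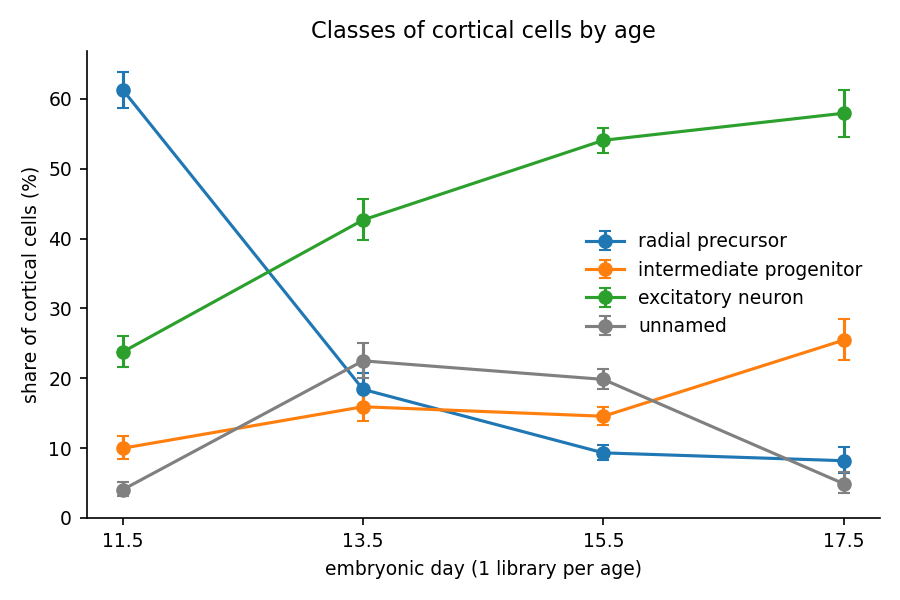
Share of the cortical cells in each class (percent, vertical axis) against embryonic day (horizontal axis), 1 library per age; points are shares and bars are exact 95% Clopper-Pearson intervals. Radial precursors went from 61.3% at E11.5 to 8.18% at E17.5.

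Genes of the astroglial list were among those that rose with age in radial precursors, and early neuroepithelial and cell-cycle genes among those that fell. By the edgeR quasi-likelihood test of a linear trend with embryonic day, 216 genes rose and 97 fell of 9173 tested (Benjamini-Hochberg adjusted, 4 libraries). Sparcl1, which encodes a secreted matrix protein of astrocytes, rose by 1.58 log2 per day (SE 0.12, edgeR adjusted p = 0.000329), from 3.87 to 1586 CPM (UMI counts scaled to a common library total). Hmga2, a chromatin protein that keeps early precursors renewing, fell by 1.30 log2 per day (SE 0.10, edgeR adjusted p = 0.000329), from 673 CPM to 0 at E17.5. The p-values rest on 4 libraries, 1 per age with the 2 labelled E15.5 batches pooled, and the 2 residual degrees of freedom hold both library spread and departure from a straight line. Age could not be separated from library. Every library but E11.5 was sorted for viable cells, and over the 3 sorted libraries 168 of the 216 rises and 35 of the 97 falls were called again. With the E15.5 table split in 2 libraries at column 3000, where the fall in depth starts anew, 366 rose and 255 fell. With 1 library left out, 339 rose and 166 fell without the E11.5 library, 617 rose and 494 fell without the E13.5 library, 93 rose and 12 fell without the E15.5 library and 39 rose and 6 fell without the E17.5 library. These fits, sorted libraries included, have 1 residual degree of freedom, so neither a lost nor a repeated call shows what carried the slope.

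Slopes of the steepest rises among genes of at least 50 CPM are in log2 per day (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted). Slco1c1 (1.82, SE 0.15, adjusted p = 0.000409) encodes a thyroid hormone transporter, Scrg1 (1.45, SE 0.14, adjusted p = 0.000724) a secreted peptide of glia, and Tnc (1.40, SE 0.10, adjusted p = 0.000329) tenascin C, a matrix protein of the stem cell niche. Next came Sepp1 (1.18, adjusted p = 0.00129), a selenium carrier, and S100a16 (1.16, adjusted p = 0.000329), a calcium-binding protein. Aldh1l1 (1.10, SE 0.15, adjusted p = 0.00440) is a folate enzyme of astrocytes and Bcan (1.05, SE 0.19, adjusted p = 0.0165) encodes brevican, a proteoglycan of brain matrix. Also among the steepest were Timp3 (1.03, adjusted p = 0.00163), an inhibitor of matrix proteases, Serpine2 (0.996, adjusted p = 0.0197), a protease inhibitor, and Apoe (0.99, SE 0.10, adjusted p = 0.00129), the lipid carrier. Levels at the 4 ages in order were 0.387, 24.2, 93.3 and 637 CPM for Tnc and 39.9, 58.0, 252 and 2379 for Apoe. Slco1c1 had 0 UMIs at E11.5 and was at least 181-fold higher at E17.5, against a floor of 3 counts. Bcan (1.09, 0.0687) did not pass without E15.5 (slope, adjusted p). With E17.5 left out Aldh1l1 (1.34, 0.0518), Bcan (1.24, 0.162) and Serpine2 (0.32, 0.668) did not pass.

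Among the steepest falls (same test and adjustment) Crabp2 (-1.21, SE 0.14, adjusted p = 0.00163) binds retinoic acid, Lrrn1 (-0.84, adjusted p = 0.0197) is a membrane protein of neuroepithelium, and Igf2bp1 (-0.55, SE 0.07, adjusted p = 0.00252) is an RNA-binding protein of early precursors. Lix1 (-0.47, adjusted p = 0.0221) belongs to early progenitors, Cdc34 (-0.44, adjusted p = 0.0217) and Ube2c (-0.45, SE 0.08, adjusted p = 0.0129) encode ubiquitin-conjugating enzymes, and Cdc20 (-0.42, adjusted p = 0.0280) activates the mitotic ubiquitin ligase. Dlgap5 (-0.43, adjusted p = 0.0336) and Birc5 (-0.40, adjusted p = 0.00794) act on the mitotic spindle, Suv39h2 (-0.42, adjusted p = 0.0118) methylates histone H3, and Eme1 (-0.42, adjusted p = 0.0154) cleaves DNA junctions. Igf2bp1 stood at 256, 122, 68.0 and 18.03 CPM in order of age, and Ube2c at 704, 405, 316 and 72.1. Hmga2 had 0 UMIs at E17.5, at least 37.4-fold lower than at E11.5, and so did Crabp2, at least 23.6-fold lower. Not called without E11.5 were Crabp2 (-0.48, 0.265), Lix1 (-0.11, 0.819), Cdc34 (-0.13, 0.801), Suv39h2 (-0.44, 0.0680) and Eme1 (-0.45, 0.126) (slope, adjusted p). Fits without E15.5 did not call Lix1 (-0.57, 0.0854), Cdc34 (-0.42, 0.141), Dlgap5 (-0.64, 0.0519), Suv39h2 (-0.48, 0.0590) and Eme1 (-0.41, 0.0854). Leaving out E17.5 gave no call for Lrrn1 (-0.86, 0.0876), Lix1 (-0.48, 0.131), Ube2c (-0.31, 0.135), Cdc34 (-0.51, 0.0609), Dlgap5 (-0.32, 0.146), Suv39h2 (-0.37, 0.0967), Eme1 (-0.41, 0.0931), Cdc20 (-0.27, 0.184) and Birc5 (-0.32, 0.131).

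**Figure D2:**
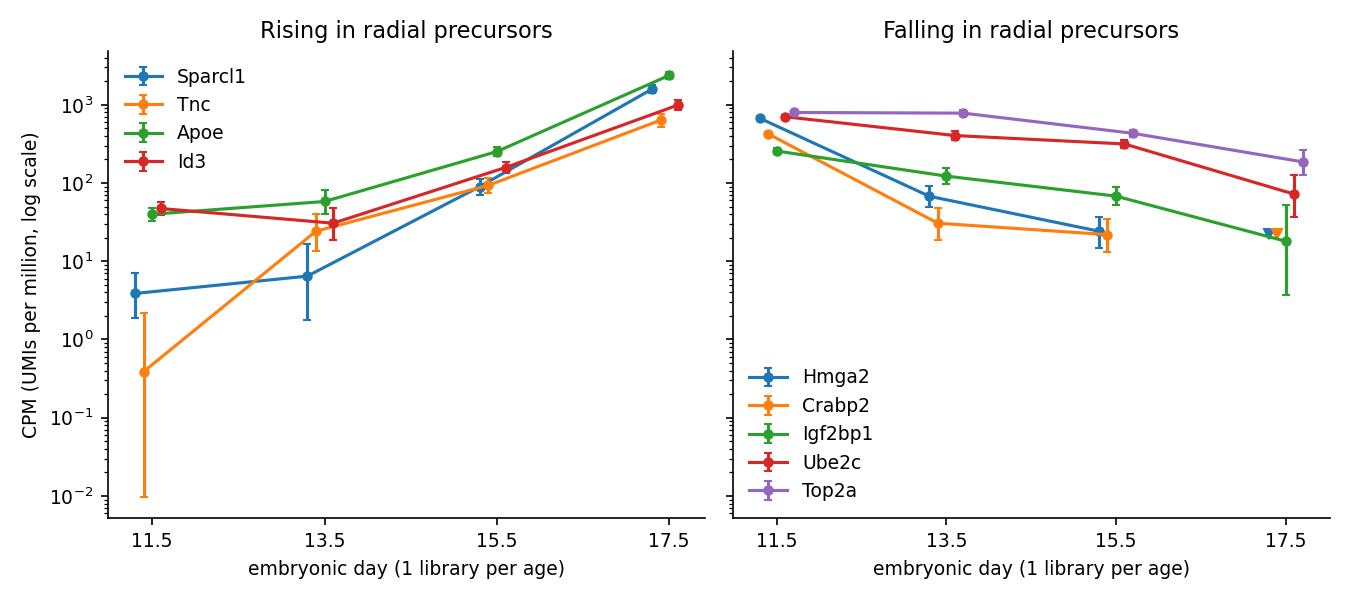
CPM (log scale, vertical axis) of 4 rising and 5 falling genes in radial precursors against embryonic day; points are 1 library per age, bars are exact Poisson 95% intervals and triangles mark the upper bound where no UMI was seen. Sparcl1 went from 3.87 to 1586 and Igf2bp1 from 256 to 18.03.

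Of the 29 measured astroglial and adult neural stem cell genes, 19 rose, 0 fell and 10 did not pass (23 rising and 0 falling within the list). Examples by the edgeR test, Benjamini-Hochberg adjusted, were Tnc, Sparcl1 and Clu (0.86, adjusted p = 0.000375), a secreted chaperone, and the list rose as a group. For the astroglial genes camera gave adjusted p = 4.94e-15, and 0.329 with an estimated correlation (below, estimated). Of the 12 BMP and Id genes, 3 rose, 1 fell and 8 did not pass (4 rising and 1 falling within the list). Id1 (0.75, SE 0.07, adjusted p = 0.000724), Id3 (0.74, adjusted p = 0.00888) and Id2 (0.32, adjusted p = 0.0125) rose while Id4 (-0.32, adjusted p = 0.00712) fell. For the BMP and Id genes camera gave adjusted p = 0.0197 (0.329 estimated). Among 20 ligands, 2 rose, 0 fell and 18 did not pass (8 rising and 1 falling within the list), with Ptn (0.58, adjusted p = 0.00579), a heparin-binding growth factor, and Tgfb2 (0.51, adjusted p = 0.0161) past the test. For the ligands camera gave adjusted p = 0.0264 (0.329 estimated). Of 18 growth factor receptors, 2 rose, 0 fell and 16 did not pass (4 rising and 0 falling within the list), namely Pdgfra (1.37, adjusted p = 0.00185), a marker of oligodendrocyte precursors, and Ednrb (0.50, adjusted p = 0.00341), the endothelin receptor. For the growth factor receptors camera gave adjusted p = 0.0469 (0.329 estimated). Without cells that held a UMI of an oligodendrocyte precursor marker the receptor list did not pass camera (adjusted p = 0.219), but that filter itself removes every Pdgfra UMI. For cholesterol and fatty acid metabolism 2 rose, 0 fell and 23 did not pass (4 rising and 0 falling within the list) of 25, namely Fabp7 (0.75, SE 0.04, adjusted p = 0.000135), a radial precursor marker, and Cpt1a (0.44, adjusted p = 0.0471), which carries fatty acids into mitochondria. For the cholesterol genes camera gave adjusted p = 0.00718 (0.407 estimated). Without E11.5 the test was not passed by Cpt1a (0.31, 0.388) and Tgfb2 (0.34, 0.0838) (slope, adjusted p). Id4 (-0.32, 0.0592), Id2 (0.32, 0.0713), Cpt1a (0.42, 0.162) and Tgfb2 (0.52, 0.0587) did not pass without E15.5. With E17.5 left out Id4 (-0.27, 0.152), Id3 (0.41, 0.217), Id2 (0.29, 0.177), Cpt1a (0.52, 0.160), Ednrb (0.40, 0.139), Ptn (0.66, 0.0824) and Tgfb2 (0.56, 0.120) did not pass. Camera without the E11.5 library no longer called the BMP and Id genes (adjusted p = 0.0935), ligands (adjusted p = 0.0606) and growth factor receptors (adjusted p = 0.0628). Camera without the E15.5 library no longer called the BMP and Id genes (adjusted p = 0.139), ligands (adjusted p = 0.112) and growth factor receptors (adjusted p = 0.117). Camera without the E17.5 library no longer called the ligands (adjusted p = 0.0722), growth factor receptors (adjusted p = 0.0722) and cholesterol genes (adjusted p = 0.792).

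Part of the cell-cycle and early neuroepithelial genes fell in radial precursors by the edgeR test with Benjamini-Hochberg adjustment. Of 26 G2/M phase genes, 0 rose, 12 fell and 14 did not pass (0 rising and 23 falling within the list), among them Ube2c, Birc5, Top2a (-0.35, adjusted p = 0.0220), a topoisomerase, and Tpx2 (-0.29, adjusted p = 0.0199), a spindle factor. For the G2/M phase genes camera gave adjusted p = 6.28e-13 (0.329 estimated). Of 26 S phase genes, 0 rose, 5 fell and 21 did not pass (0 rising and 20 falling within the list). These included Rrm2 (-0.39, adjusted p = 0.0119), Dut (-0.28, adjusted p = 0.0274), Prim1 (-0.29, adjusted p = 0.0278) and Hells (-0.32, adjusted p = 0.0285), which act in nucleotide supply, priming and chromatin at the fork. For the S phase genes camera gave adjusted p = 4.80e-11 (0.329 estimated). Of 11 early neuroepithelial and let-7 target genes, 0 rose, 5 fell and 6 did not pass (0 rising and 8 falling within the list), with Hmga2, Crabp2, Igf2bp1 and Igf2bp2 (-0.40, adjusted p = 0.0116) among them. For the early neuroepithelial genes camera gave adjusted p = 7.13e-06 (0.329 estimated). For glycolysis and hypoxia 1 rose, 4 fell and 15 did not pass (2 rising and 5 falling within the list) of 20. Slc16a3 (-1.03, adjusted p = 0.00380), a lactate transporter, Pkm (-0.25, adjusted p = 0.0215) and Mif (-0.20, adjusted p = 0.0385) fell, and Egln3 (0.50, adjusted p = 0.0128), an oxygen sensor, rose. For the glycolysis genes camera gave adjusted p = 0.0222 (0.329 estimated). Not called without E11.5 was Igf2bp2 (-0.42, 0.0820) (slope, adjusted p). Fits without E15.5 did not call Dut (-0.31, 0.0820), Prim1 (-0.31, 0.109), Hells (-0.38, 0.0769), Tpx2 (-0.29, 0.108), Top2a (-0.37, 0.0918), Igf2bp2 (-0.42, 0.0792), Pkm (-0.27, 0.0854) and Mif (-0.21, 0.141). Leaving out E17.5 gave no call for Rrm2 (-0.30, 0.153), Dut (-0.20, 0.312), Prim1 (-0.23, 0.284), Hells (-0.22, 0.3001), Tpx2 (-0.25, 0.218), Top2a (-0.24, 0.302), Igf2bp2 (-0.38, 0.0921), Egln3 (0.49, 0.153), Pkm (-0.20, 0.284) and Mif (-0.15, 0.400). Camera without the E11.5 library no longer called the glycolysis genes (adjusted p = 0.706). Camera without the E15.5 library no longer called the glycolysis genes (adjusted p = 0.0811).

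Most members of the signalling and patterning lists did not pass the edgeR test in radial precursors (Benjamini-Hochberg adjusted). Of 16 Notch genes, 1 rose, 0 fell and 15 did not pass (3 rising and 0 falling within the list), the riser being Dner (0.70, adjusted p = 0.00417), a neuronal Notch ligand that acts on glia, and Dll3 (0.52, adjusted p = 0.0511) not past it. For the Notch genes camera gave adjusted p = 0.270. Of 20 Wnt genes, 1 rose, 0 fell and 19 did not pass (1 rising and 0 falling within the list), the riser being Dkk3 (0.75, adjusted p = 0.00622), a secreted Wnt modulator, beside Sfrp1 (-0.11, adjusted p = 0.163) and Tcf7l1 (-0.23, adjusted p = 0.129). For the Wnt genes camera gave adjusted p = 0.698. Of 22 cortical patterning factors, 0 rose, 0 fell and 22 did not pass (1 rising and 4 falling within the list), and slopes were Zeb2 (0.31, adjusted p = 0.0514), Otx1 (-0.27, adjusted p = 0.0647) and Lhx2 (-0.24, adjusted p = 0.0733). For the patterning factors camera gave adjusted p = 0.313. Among the 12 imprinted growth genes 0 rose, 0 fell and 12 did not pass (3 rising and 2 falling within the list), with H19 (0.39, adjusted p = 0.0584) and Peg10 (-0.41, adjusted p = 0.0584). For the imprinted genes camera gave adjusted p = 0.627. Of the 81 cytosolic ribosomal proteins, 0 rose, 1 fell and 80 did not pass (none within the list), the faller being Rps4y2 (-0.59, adjusted p = 0.0301). For the ribosomal proteins camera gave adjusted p = 0.0916. Of 9 mitochondrially encoded genes, 0 rose, 0 fell and 9 did not pass (none within the list), with mt-Nd1 (-0.09, adjusted p = 0.218). For the mitochondrial genes camera gave adjusted p = 0.184. Without cells that held a UMI of an oligodendrocyte precursor marker, the ribosomal list passed camera (adjusted p = 0.0416). Without E17.5 the test was not passed by Dner (0.67, 0.115), Dkk3 (0.72, 0.146) and Rps4y2 (-0.62, 0.113) (slope, adjusted p).

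Some transcripts of neurons also rose with age in the radial precursor cells by the edgeR test (Benjamini-Hochberg adjusted). Of 22 synaptic and axonal genes, 8 rose, 0 fell and 14 did not pass (14 rising and 0 falling within the list). They included Nsg2 (0.67, adjusted p = 0.00584) and Gria2 (0.50, adjusted p = 0.00712), a glutamate receptor subunit, and the neuronal markers Mapt (0.81, adjusted p = 0.000880) and Stmn2 (0.34, adjusted p = 0.0107). For the synaptic genes camera gave adjusted p = 1.97e-09 (0.329 estimated). Of 12 neuronal transcripts listed as a check on precursors, 5 rose, 0 fell and 7 did not pass (7 rising and 0 falling within the list), among them Rtn1 (0.56, adjusted p = 0.00163), an endoplasmic reticulum protein, and Gap43 (0.31, adjusted p = 0.0166) of growth cones. For the neuronal transcripts camera gave adjusted p = 2.48e-05 (0.329 estimated). Of 13 upper-layer neuron genes, 2 rose, 0 fell and 11 did not pass (5 rising and 1 falling within the list), namely Pou3f1 (0.82, adjusted p = 0.00480) and the marker Mef2c (0.74, adjusted p = 0.0173). For the upper-layer genes camera gave adjusted p = 0.0197 (0.329 estimated). Of 11 deep-layer genes, 0 rose, 0 fell and 11 did not pass (none within the list), with Ldb2 (0.43, adjusted p = 0.0948). For the deep-layer genes camera gave adjusted p = 0.313. Of 5 interneuron transcripts, all markers, 0 rose, 0 fell and 5 did not pass (1 rising and 0 falling within the list), with Dlx6os1 (0.47, adjusted p = 0.0980). For the interneuron transcripts camera gave adjusted p = 0.313. Of 3 hemoglobin genes, which are erythroid markers, 0 rose, 0 fell and 3 did not pass (2 rising and 0 falling within the list), with Hbb-bs (0.66, adjusted p = 0.0868). Mef2c (0.67, 0.154), Stmn2 (0.34, 0.0587) and Gap43 (0.30, 0.0850) did not pass without E15.5 (slope, adjusted p). With E17.5 left out Mef2c (0.93, 0.0518), Gria2 (0.57, 0.0653), Stmn2 (0.39, 0.0884) and Gap43 (0.34, 0.130) did not pass. Camera without the E11.5 library no longer called the upper-layer genes (adjusted p = 0.201). Camera without the E15.5 library no longer called the upper-layer genes (adjusted p = 0.163).

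Immediate early genes, which respond to stimuli and to tissue dissociation, rose in part in radial precursors by the edgeR test (Benjamini-Hochberg adjusted). Of 13 dissociation stress and immediate early genes, 3 rose, 0 fell and 10 did not pass (8 rising and 0 falling within the list), namely Fos (0.67, adjusted p = 0.00129), Junb (0.80, adjusted p = 0.0240) and Egr1 (0.73, adjusted p = 0.0465). For the stress genes camera gave adjusted p = 4.98e-05 (0.329 estimated). Fos stood at 45.3, 209.5, 382 and 877 CPM in order of age. Dusp1 (0.38, adjusted p = 0.0641) did not pass the test. Of 10 precursor transcripts, 4 rose, 1 fell and 5 did not pass (6 rising and 1 falling within the list), namely Dbi (0.41, adjusted p = 0.00539) and the markers Slc1a3 (0.75, adjusted p = 0.000329) and Mfge8 (0.84, adjusted p = 0.00128), beside Fabp7, with Id4 falling. For the precursor transcripts camera gave adjusted p = 0.00224 (0.329 estimated). Fabp7, the gene with the smallest p of the class, stood at 786, 2982, 6280 and 20291 CPM in order of age. Not called without E15.5 was Egr1 (0.75, 0.115) (slope, adjusted p). Fits without E17.5 did not call Egr1 (0.97, 0.141) and Dbi (0.49, 0.0518).

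**Figure D3:**
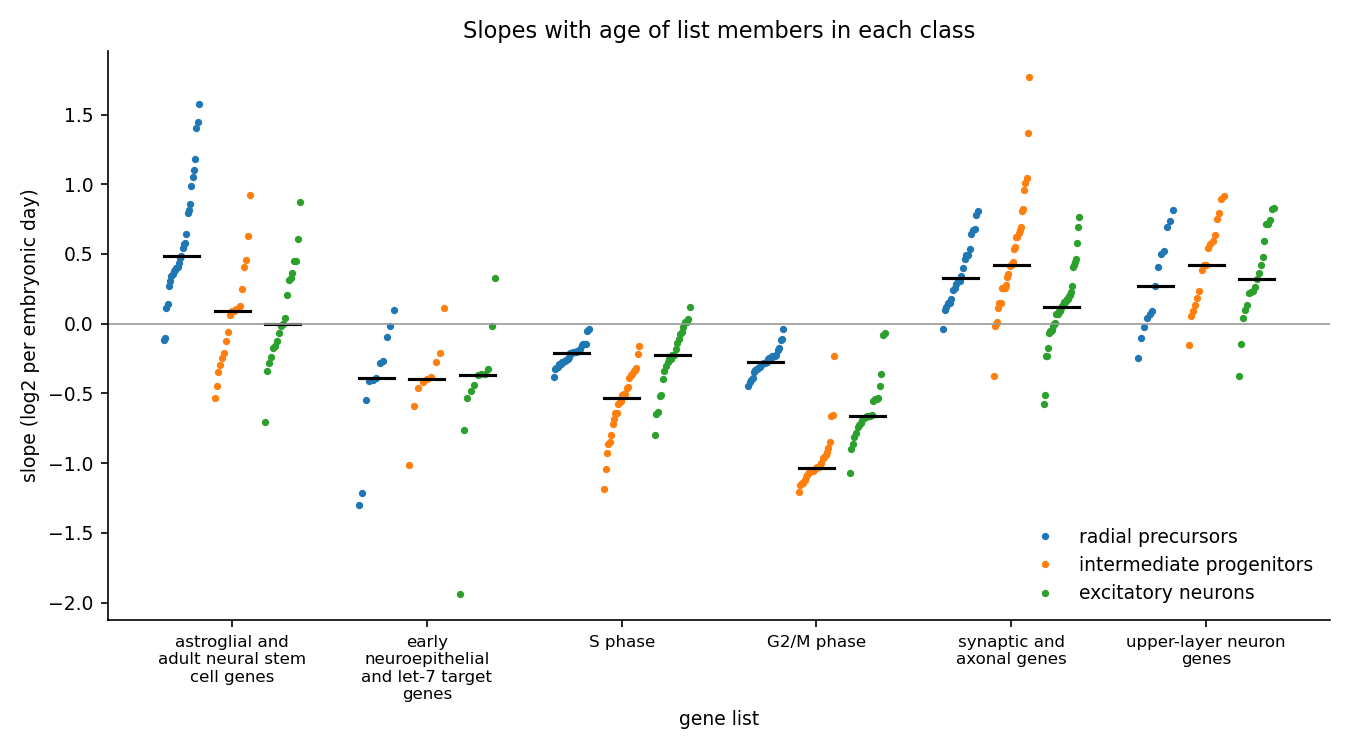
Slope with embryonic day (log2 per day, vertical axis) of each tested member of 6 gene lists (horizontal axis) in radial precursors, intermediate progenitors and excitatory neurons; each point is 1 gene fitted over 4 libraries and black lines are medians. The median of the astroglial list was 0.49 in radial precursors and that of the G2/M list was -1.03 in intermediate progenitors.

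Slopes of radial precursors were compared with those of the other classes in 1 edgeR model with the library as a block, a comparison chosen after the data were seen. Of the 216 rising genes, 28 rose more steeply than in intermediate progenitors and 42 more steeply than in excitatory neurons (Benjamini-Hochberg adjusted). The slope difference was positive for 186 and 206 of them, a sign their selection favours, and for 4602 and 4719 of all 9173 genes. Apoe, Timp3, Serpine2 and S100a16 were among those steeper than in intermediate progenitors. Of the 97 falling genes, 0 fell more steeply than in intermediate progenitors (unadjusted p under 0.05 for 1076 of all genes, either direction; no other tool was run on this comparison), and 7 more steeply than in excitatory neurons. The slope difference of the falling genes was negative for 35 and 60 of them.

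Fewer radial precursors carried transcripts of dividing cells at later ages. After thinning every cell to 1000 UMIs, the share of radial precursors with at least 2 UMIs of the G2/M list was 89.7% at E11.5 (87.2 to 91.8%, 642 of 716 cells), 68.8% at E13.5 (61.6 to 75.4%, 128 of 186 cells), 63.2% at E15.5 (57.1 to 69.0%, 168 of 266 cells) and 27.9% at E17.5 (17.7 to 40.1%, 19 of 68 cells). For the S phase list, of genes of DNA replication, the share was 95.7%, 83.9%, 71.1% and 39.7%. The E17.5 share over the E11.5 share was 0.312 (0.213 to 0.457) for G2/M and 0.415 (0.310 to 0.556) for S phase. In cells named excitatory neurons, taken as a background of cells that do not divide, the G2/M share was 28.5%, 5.48%, 4.52% and 2.26%, and the S share 35.3%, 11.2%, 10.9% and 10.9%. The background ratio of E17.5 to E11.5 was 0.0795 for G2/M and 0.309 for S phase. With 1 list UMI the S ratio was higher in neurons (0.658) than in radial precursors (0.596), and so it was without thinning (0.692 and 0.570), the reverse of the reported order. Free RNA of dividing cells stayed open as part of the change. Median depth of the class was 2386 UMIs per cell at E11.5, 2598 at E13.5, 2635 at E15.5 and 2013 at E17.5.

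**Figure D4:**
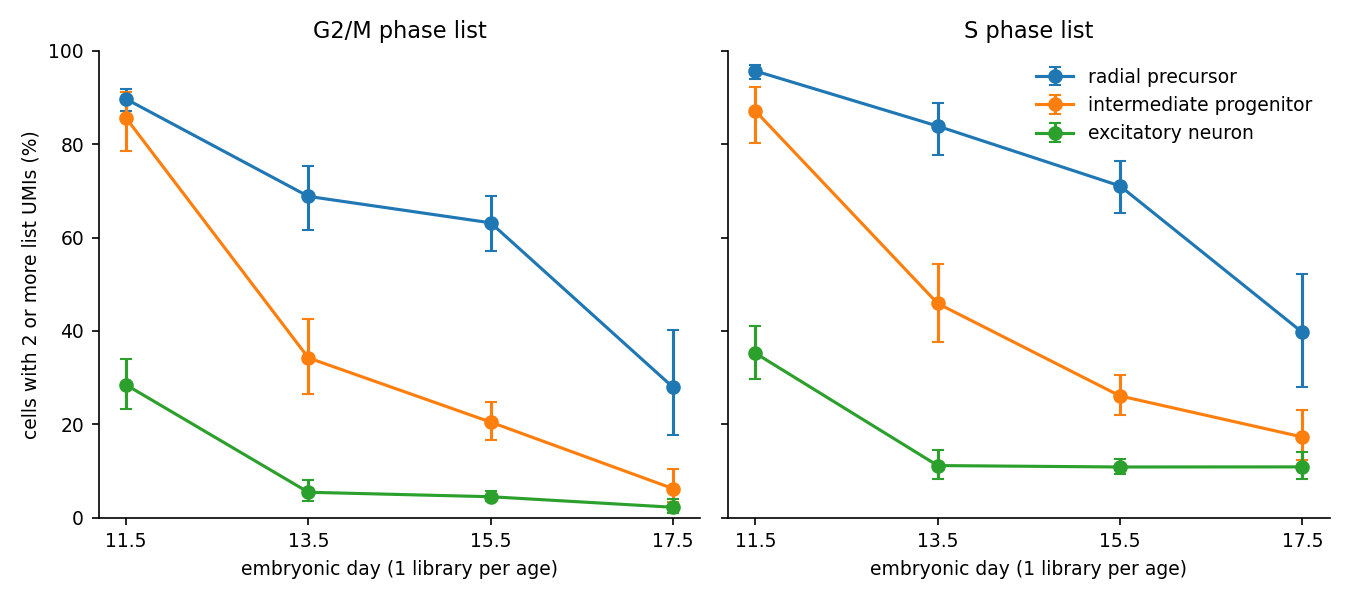
Share of cells with at least 2 UMIs of the G2/M list or the S phase list after thinning to 1000 UMIs per cell (percent, vertical axes) against embryonic day, 1 library per age; bars are exact 95% Clopper-Pearson intervals. The G2/M share of radial precursors was 89.7% at E11.5 and 27.9% at E17.5.

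Expression profiles of radial precursors differed most between E11.5 and E17.5. Across 4377 genes, which are not independent replicates, Pearson r on log2 CPM was 0.619 for that pair, with all libraries thinned to 166429 UMIs. Neighbouring ages gave 0.824 (E11.5 and E13.5), 0.878 (E13.5 and E15.5) and 0.814 (E15.5 and E17.5). The remaining pairs gave 0.794 (E11.5 and E15.5) and 0.733 (E13.5 and E17.5). With genes of at least 200 CPM only, r for E11.5 and E17.5 was 0.472.

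Among cells named intermediate progenitors, mitotic genes fell with age and some synaptic and axonal genes rose. By the edgeR quasi-likelihood trend test, 273 genes rose and 258 fell of 7921 tested (Benjamini-Hochberg adjusted, 4 libraries with 141, 179, 430 and 224 cells in order of age). Ube2c fell by 1.08 log2 per day (SE 0.08, edgeR adjusted p = 0.00109), from 962 to 4.95 CPM. Gria2 rose by 1.01 log2 per day (SE 0.06, edgeR adjusted p = 0.000788), from 34.1 to 2268 CPM. The E17.5 cells came from a single cluster led also by Sema3c, Unc5d and Neurod1, genes that led unnamed clusters at E13.5 and E15.5. With 1 library left out, 265 rose and 170 fell without the E11.5 library, 663 rose and 466 fell without the E13.5 library, 67 rose and 103 fell without the E15.5 library and 123 rose and 200 fell without the E17.5 library. Of the calls without E17.5, only 44 rises and 170 falls were among the 273 and 258 reported. With 1 residual degree of freedom, neither a lost nor a repeated call shows what carried the slope.

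The steepest rises in intermediate progenitors (log2 per day, edgeR test, Benjamini-Hochberg adjusted) included Chl1 (1.17, SE 0.11, adjusted p = 0.00219), a neural adhesion molecule, Sema3c (1.09, adjusted p = 0.00302), a secreted guidance cue, Unc5d (0.91, adjusted p = 0.0167), a netrin receptor, and Ppfia2 (0.82, adjusted p = 0.00287), a scaffold of the presynapse. Others were Bhlhe22 (1.001, adjusted p = 0.00305), Rbfox1 (0.91, adjusted p = 0.00865) and Pcp4 (1.01, adjusted p = 0.0277). Prkar1b (0.92, adjusted p = 0.00615) and Gpr85 (0.90, adjusted p = 0.00426) rose too. So did Jph4 (0.89, adjusted p = 0.00512) and Ly6h (0.86, adjusted p = 0.00865). The steepest falls were Dlgap5 (-1.51, SE 0.14, adjusted p = 0.00231), Plk1 (-1.21, adjusted p = 0.00109), Cdca8 (-1.16, adjusted p = 0.00219), Ccnb1 (-1.15, adjusted p = 0.00109) and Aurkb (-1.15, adjusted p = 0.00446). Bub1 (-1.12, adjusted p = 0.00426), Birc5 (-1.06, adjusted p = 0.00302) and Hmmr (-1.06, adjusted p = 0.00286) act at the kinetochore and spindle. Gmnn (-1.14, adjusted p = 0.00419) limits replication origins, Rrm2 (-1.19, adjusted p = 0.00286) supplies nucleotides and Top2a (-1.14, adjusted p = 0.00731) untangles chromosomes. Leaving out E11.5 gave no call for Pcp4 (0.67, 0.138) (slope, adjusted p).

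Every one of the 26 measured G2/M genes passed the edgeR test in intermediate progenitors (Benjamini-Hochberg adjusted): 0 rose, 26 fell and 0 did not pass (0 rising and 26 falling within the list). For the G2/M phase genes camera gave adjusted p = 1.94e-27, and 0.508 with an estimated correlation. Examples beside Ube2c were Cenpa (-0.96, adjusted p = 0.00109), Ccnb1 and Plk1. Of 26 S phase genes, 0 rose, 19 fell and 7 did not pass (0 rising and 26 falling within the list), with Rrm2, Rrm1 (-0.58, adjusted p = 0.00373), Hells (-0.80, adjusted p = 0.00445) and Uhrf1 (-0.85, adjusted p = 0.00598) as examples. For the S phase genes camera gave adjusted p = 2.93e-19 (0.527 estimated). Of 9 early neuroepithelial genes, 0 rose, 4 fell and 5 did not pass (0 rising and 6 falling within the list), namely Ccnd1 (-1.01, adjusted p = 0.00109), a cyclin, Igf2bp1 (-0.59, adjusted p = 0.00438), Igf2bp2 (-0.42, adjusted p = 0.0122) and Igf2bp3 (-0.46, adjusted p = 0.00731). For the early neuroepithelial genes camera gave adjusted p = 1.78e-05 (0.508 estimated). Of 12 Notch genes, 0 rose, 6 fell and 6 did not pass (0 rising and 7 falling within the list), with Dll3 (-0.49, adjusted p = 0.00782), Dll1 (-0.58, adjusted p = 0.0171) and the radial precursor markers Hes1 (-0.79, adjusted p = 0.00782) and Hes5 (-0.48, adjusted p = 0.0146). For the Notch genes camera gave adjusted p = 1.78e-05 (0.508 estimated). Of 10 precursor transcripts, 0 rose, 3 fell and 7 did not pass (0 rising and 4 falling within the list), namely Hes1, Hes5 and the marker Vim (-0.59, adjusted p = 0.0255). For the precursor transcripts camera gave adjusted p = 0.00729 (0.546 estimated). For imprinted growth genes 0 rose, 2 fell and 8 did not pass (2 rising and 4 falling within the list) of 10, namely Cdkn1c (-0.48, adjusted p = 0.00871), a brake on division, and Mest (-0.52, adjusted p = 0.0389). For the imprinted genes camera gave adjusted p = 0.306. Among 16 glycolysis genes 0 rose, 3 fell and 13 did not pass (0 rising and 4 falling within the list), namely Ldha (-0.29, adjusted p = 0.0220), Pkm (-0.21, adjusted p = 0.0481) and Tpi1 (-0.23, adjusted p = 0.0495). For the glycolysis genes camera gave adjusted p = 0.175. Without E11.5 the test was not passed by Igf2bp3 (-0.40, 0.102), Igf2bp2 (-0.49, 0.0560), Dll3 (-0.52, 0.0510), Pkm (-0.19, 0.155), Tpi1 (-0.27, 0.109), Cdkn1c (-0.44, 0.0716) and Mest (-0.04, 0.866) (slope, adjusted p). Igf2bp2 (-0.43, 0.0545), Hes5 (-0.44, 0.0632), Dll1 (-0.59, 0.0660), Ldha (-0.28, 0.118), Pkm (-0.21, 0.189), Tpi1 (-0.22, 0.189) and Mest (-0.45, 0.132) did not pass without E15.5. With E17.5 left out Igf2bp2 (-0.37, 0.0552), Ldha (-0.27, 0.158), Pkm (-0.20, 0.283), Tpi1 (-0.23, 0.248) and Vim (-0.33, 0.0530) did not pass.

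A minority of synaptic, upper-layer and neuronal genes rose in intermediate progenitors by the edgeR test (Benjamini-Hochberg adjusted). Of 32 synaptic and axonal genes, 15 rose, 0 fell and 17 did not pass (23 rising and 1 falling within the list). Examples were Gria2, Cntn2 (0.81, adjusted p = 0.00302), Gabra2 (1.77, adjusted p = 0.00305) and the marker Mapt (1.05, adjusted p = 0.00109). For the synaptic genes camera gave adjusted p = 1.89e-11 (0.527 estimated). Of 17 upper-layer genes, 7 rose, 0 fell and 10 did not pass (8 rising and 0 falling within the list), with Cux2 (0.63, adjusted p = 0.0147), 9130024F11Rik (0.80, adjusted p = 0.00631) and the marker Mef2c (0.89, adjusted p = 0.0104). For the upper-layer genes camera gave adjusted p = 5.46e-07 (0.508 estimated). Of 10 deep-layer genes, 1 rose, 0 fell and 9 did not pass (2 rising and 0 falling within the list), namely the marker Bcl11b (0.23, adjusted p = 0.0493). For the deep-layer genes camera gave adjusted p = 0.555. Of 12 neuronal transcripts, 4 rose, 0 fell and 8 did not pass (6 rising and 0 falling within the list), namely Rtn1 (0.46, adjusted p = 0.00686) and the markers Dcx (0.30, adjusted p = 0.0167), Neurod2 (0.70, adjusted p = 0.0331) and Mapt. For the neuronal transcripts camera gave adjusted p = 0.000303 (0.546 estimated). Of 5 interneuron transcripts, 1 rose, 0 fell and 4 did not pass (2 rising and 0 falling within the list). The riser was the marker Npy (1.55, adjusted p = 0.00219). For the interneuron transcripts camera gave adjusted p = 0.0673. All 3 tested hemoglobin genes, erythroid markers, rose: Hba-a1 (1.04, adjusted p = 0.00219), Hbb-bs (1.14, adjusted p = 0.00512) and Hbb-bt (1.19, adjusted p = 0.00512) (3 rising within the list). Free RNA was not tested in this class and stays open for these and other rises. Not called without E11.5 were Bcl11b (0.21, 0.172) and Cux2 (0.55, 0.0545) (slope, adjusted p). Fits without E15.5 did not call Bcl11b (0.23, 0.134), Dcx (0.30, 0.0754) and Neurod2 (0.70, 0.0827). Leaving out E17.5 gave no call for Bcl11b (0.22, 0.306), Cux2 (0.56, 0.197) and Dcx (0.29, 0.105).

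The remaining lists had few members past the edgeR test in intermediate progenitors (Benjamini-Hochberg adjusted), and none passed camera. Of 19 astroglial genes, 1 rose, 1 fell and 17 did not pass (3 rising and 3 falling within the list), with Sparcl1 (0.92, adjusted p = 0.0112) rising and Sparc (-0.54, adjusted p = 0.0381) falling. For the astroglial genes camera gave adjusted p = 0.866. Of 19 patterning factors, 1 rose, 3 fell and 15 did not pass (8 rising and 5 falling within the list), with Zeb2 (0.35, adjusted p = 0.0142) rising and Emx2 (-0.38, adjusted p = 0.0188), Tfap2c (-0.46, adjusted p = 0.0204) and the marker Sox2 (-0.37, adjusted p = 0.0272) falling. For the patterning factors camera gave adjusted p = 0.663. Of 15 ligands, 1 rose, 2 fell and 12 did not pass (4 rising and 2 falling within the list), with Sema3c, Dll3 and Dll1. For the ligands camera gave adjusted p = 0.663. Of 6 BMP and Id genes, 1 rose, 0 fell and 5 did not pass (1 rising and 0 falling within the list), namely Id2 (0.35, adjusted p = 0.0188). For the BMP and Id genes camera gave adjusted p = 0.752. Of 10 stress genes, 1 rose, 0 fell and 9 did not pass (1 rising and 0 falling within the list), namely Fos (0.49, adjusted p = 0.0483). For the stress genes camera gave adjusted p = 0.0625. Of 10 Wnt genes, 0 rose, 0 fell and 10 did not pass (2 rising and 2 falling within the list), with Sfrp1 (-0.25, adjusted p = 0.0551). For the Wnt genes camera gave adjusted p = 0.375. Of 12 receptors, 0 rose, 0 fell and 12 did not pass (0 rising and 1 falling within the list), with Cntfr (-0.56, adjusted p = 0.0534). For the growth factor receptors camera gave adjusted p = 0.663. Of 21 cholesterol and fatty acid genes, 0 rose, 0 fell and 21 did not pass (none within the list), with Acadm (-0.36, adjusted p = 0.0913). For the cholesterol genes camera gave adjusted p = 0.375. Of 9 mitochondrially encoded genes, 0 rose, 0 fell and 9 did not pass (none within the list), with mt-Co1 (0.13, adjusted p = 0.221), and ribosomal proteins 0 rose, 0 fell and 78 did not pass (none within the list) of 78, with Rps27l (-0.24, adjusted p = 0.0534). For the mitochondrial genes and the ribosomal proteins camera gave adjusted p = 0.997 and 0.663. Without E11.5 the test was not passed by Sparc (-0.70, 0.0875), Zeb2 (0.33, 0.0658), Emx2 (-0.39, 0.102) and Fos (0.36, 0.284) (slope, adjusted p). Sparc (-0.51, 0.154), Id2 (0.35, 0.0695), Tfap2c (-0.50, 0.0577) and Sox2 (-0.36, 0.101) did not pass without E15.5. With E17.5 left out Sparc (-0.50, 0.161), Id2 (0.27, 0.139), Zeb2 (0.34, 0.108), Emx2 (-0.29, 0.122), Tfap2c (-0.32, 0.110) and Sox2 (-0.30, 0.164) did not pass.

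No gene passed the trend test in excitatory neurons. By the edgeR quasi-likelihood test 0 genes rose and 0 fell of 10247 (smallest Benjamini-Hochberg adjusted p = 0.0596), with 1527 at an unadjusted p under 0.05, over 4 libraries with 336, 480, 1598 and 510 cells in order of age. The DESeq2 Wald test called 79 rising and 110 falling genes. Without the E11.5 library the edgeR test called 218 rising and 131 falling, and without the E13.5 library 35 and 63. Without the clusters that failed the first marker check (152 cortical cells at E11.5, 492 at E15.5) 2 genes rose and 4 fell. With the E15.5 table taken as 2 libraries 30 genes rose and 66 fell. Genes with the largest ratios of E17.5 to E11.5 are given as values, in CPM at E11.5 and at E17.5. They were Nfix (7.03 and 712), Ptn (35.2 and 1818), Camk2b (4.22 and 289) and Mpped1 (16.9 and 706). Others were Ndrg1 (0 and 175.4), Sybu (0 and 132), Dync1i1 (7.03 and 379), Limch1 (14.1 and 558), Bend6 (2.81 and 212), Chl1 (7.03 and 322), Id2 (74.6 and 1839.7) and Tiam2 (0 and 98.3).

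Largest the other way were Crabp2 (1117 and 2.36 CPM at E11.5 and E17.5), Nxph4 (249 and 4.72), a neurexin ligand, Cntnap2 (1049.5 and 41.7), an axonal protein, and Emx2 (274 and 10.2), a patterning factor. Others were St18 (183 and 2.36), Chd7 (212 and 9.44), Dll3 (222 and 13.4), Rnd2 (287 and 19.7), Snhg11 (211 and 13.4), Cxxc5 (280.0 and 20.5), Tmem176b (122 and 7.08) and Foxp2 (225 and 16.5). The deep-layer marker Tbr1 stood at 849.8, 437, 306 and 131 CPM in order of age (slope -0.43 log2 per day, edgeR adjusted p = 0.132).

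Of every list, 0 measured members rose and 0 fell in excitatory neurons by the edgeR test adjusted over all genes (Benjamini-Hochberg). The 23 (0 rising and 20 falling within the list) G2/M genes included Mki67 at 88.6 CPM at E11.5 and 4.72 at E17.5, beside Cenpe and Birc5. For the G2/M phase genes camera gave adjusted p = 6.80e-13, and 0.493 with an estimated correlation. S phase genes measured were 23 (0 rising and 6 falling within the list), with Hells and Uhrf1 of smallest p. For the S phase genes camera gave adjusted p = 9.29e-06 (0.473 estimated). Early neuroepithelial genes were 11 (0 rising and 8 falling within the list), among them Igf2bp1 and Ccnd1. For the early neuroepithelial genes camera gave adjusted p = 1.48e-05 (0.428 estimated). Notch genes were 11 (0 rising and 3 falling within the list), among them Mfng and Hey1. For the Notch genes camera gave adjusted p = 0.00163 (0.552 estimated). Upper-layer genes were 19 (5 rising and 0 falling within the list), among them Dok5, 7.03 CPM at E11.5 and 164 at E17.5, and Limch1. For the upper-layer genes camera gave adjusted p = 2.43e-05 (0.428 estimated). Synaptic and axonal genes were 36 (10 rising and 2 falling within the list), among them Nrp1 and Ina. For the synaptic genes camera gave adjusted p = 0.00663 (0.555 estimated). Patterning factors were 20 (0 rising and 3 falling within the list), among them Tfap2c and the marker Pax6. For the patterning factors camera gave adjusted p = 0.0391 (0.555 estimated). Imprinted genes were 12 (0 rising and 3 falling within the list), among them Nnat at 6329.5 and 1591 CPM, and Grb10. For the imprinted genes camera gave adjusted p = 0.00173 (0.428 estimated). Camera without the E11.5 library no longer called the S phase genes (adjusted p = 0.0764), Notch genes (adjusted p = 0.358), synaptic genes (adjusted p = 0.181) and patterning factors (direction reversed, adjusted p = 0.981). Without E13.5 or E15.5 it no longer called the patterning factors (adjusted p = 0.0651 and 0.172).

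Ribosomal proteins measured in excitatory neurons were 81 (none within the list), among them Rpl30. For the ribosomal proteins camera gave adjusted p = 0.00794 (0.428 estimated). Interneuron transcripts, all markers, were 9 (2 rising and 0 falling within the list), among them Npy with 0 CPM at E11.5 and 176 at E17.5. For the interneuron transcripts camera gave adjusted p = 0.000964 (0.473 estimated). Precursor transcripts were 8 (1 rising and 2 falling within the list), among them the marker Vim at 703 and 31.5. For the precursor transcripts camera gave adjusted p = 0.0379 (0.473 estimated). Camera without the E11.5 library no longer called the precursor transcripts (adjusted p = 0.181). Camera without the E17.5 library no longer called the interneuron transcripts (direction reversed, adjusted p = 0.923) and precursor transcripts (adjusted p = 0.119). Astroglial genes were 19 (1 rising and 0 falling within the list), and ligands 24 (4 rising and 5 falling within the list). For the astroglial genes and the ligands camera gave adjusted p = 0.372 and 0.863. Deep-layer genes were 16 (0 rising and 1 falling within the list), among them Tbr1 and Foxp2, and Wnt genes 15 (1 rising and 1 falling within the list). For the deep-layer genes and the Wnt genes camera gave adjusted p = 0.367 and 0.276. BMP and Id genes were 8 (none within the list), and receptors 11 (1 rising and 0 falling within the list). For the BMP and Id genes and the growth factor receptors camera gave adjusted p = 0.790 and 0.662. Glycolysis genes were 19 (none within the list), and cholesterol and fatty acid genes 22 (none within the list). For the glycolysis genes and the cholesterol genes camera gave adjusted p = 0.554 and 0.774. Stress genes were 12 (none within the list), and mitochondrially encoded genes 9 (none within the list). For the stress genes and the mitochondrial genes camera gave adjusted p = 0.114 and 0.554. Neuronal transcripts were 12 (0 rising and 1 falling within the list), among them Ina and the marker Mapt. For the neuronal transcripts camera gave adjusted p = 0.554. Hemoglobin genes were 4 (3 rising and 1 falling within the list), among them the marker Hbb-y.

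The authors' cortical tables left out almost all inhibitory neurons, the cells that migrate into the cortex from the ganglionic eminences and carry markers such as Gad1 and Gad2. The share left out was 98.8% at E11.5, 100% at E13.5, 99.5% at E15.5 and 98.8% of 561 cells (97.4 to 99.5%) at E17.5. Ganglionic eminence precursors, with markers such as Dlx2, were left out at 92.0%, 96.2%, 86.8% and 99.1%. Striatal projection neurons were left out at 100%, 99.6% and 97.4% from E13.5 on. Cajal-Retzius neurons, which secrete reelin, were left out at 93.9%, 100%, 100% and 16.7% of 18 cells (3.58 to 41.4%). Erythroid cells were left out at 98.0%, 97.7%, 100% and 100%, and microglia at 100%, 100% and 95% from E13.5 on. Fibroblasts were left out at 100% at E11.5 and 100% at E15.5. Of radial precursors 11.4%, 6.76%, 6.14% and 6.49% were left out. For intermediate progenitors the shares were 5.37%, 10.1%, 2.71% and 3.86%, and for excitatory neurons 2.61%, 14.1%, 14.1% and 5.03%. At Leiden resolution 1 no cluster was named for oligodendrocyte precursors, endothelial cells, pericytes, diencephalic neurons or choroid plexus. At resolution 0.5 a cluster of 31 E11.5 cells was named endothelial but failed the marker check, and at resolution 2 a cluster of 10 E17.5 cells was named oligodendrocyte precursors.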

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

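Tests chosen only after the results were seen were the slope differences between classes, the tests of handling, of oligodendrocyte precursors and of a difference shared by all cells of a library, and the count over other orderings of the libraries.

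A difference between classes drew attention to 8 genes, each tested in an edgeR model with the library as a block and Benjamini-Hochberg adjustment. The rise per day was steeper in radial precursors than in intermediate progenitors by log2 1.06 (SE 0.20, adjusted p = 0.00772) for S100a16, 1.04 (SE 0.26, adjusted p = 0.0463) for Timp3, 0.97 (SE 0.18, adjusted p = 0.00848) for Serpine2 and 0.90 (SE 0.15, adjusted p = 0.00409) for Apoe. Against excitatory neurons it was steeper by 1.06 (SE 0.15, adjusted p = 0.0257) for Timp3 and 0.76 (SE 0.13, adjusted p = 0.0377) for Apoe. The mitotic genes fell less steeply in radial precursors than in intermediate progenitors, by 0.68 (SE 0.08, adjusted p = 0.000221) for Ube2c, 1.15 (SE 0.16, adjusted p = 0.000988) for Dlgap5, 0.73 (SE 0.14, adjusted p = 0.0101) for Cdc20 and 0.68 (SE 0.10, adjusted p = 0.00130) for Birc5.

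Astroglial genes rose with age in radial precursors, 19 of 29 measured. At Leiden resolution 2, 10 E17.5 cells of the class, 8 of them cortical, were named oligodendrocyte precursors. They held 0.281 times (0.215 to 0.373, cells resampled) the astroglial CPM of the other radial precursors at E17.5, so such cells lower the list, which argues against them as the source. Without the E17.5 library the mean slope was 0.621 log2 per day (SE 0.0923), though only 4 of 28 genes passed over the 3 libraries left. Without cells that held a UMI of such a marker (20 of 72 at E17.5 and 9 of 867 at E11.5) it was 0.618 (SE 0.0818), and 18 of the 19 passed. That alone decides nothing, since such cells can lack the UMI. A library difference shared by all cells would give neurons the same slope. But the mean over all 29 genes was 0.516 log2 per day higher in radial precursors (0.615) than in excitatory neurons (SE over genes 0.0676). In neurons only 19 passed the count filter (mean 0.0803). Means of tested members were 0.0517 in intermediate progenitors, 0.0700 in inhibitory neurons and 0.199 in ganglionic eminence precursors (camera adjusted p = 0.000239). Age (1 library each) and astrocytes named radial precursors (no astrocyte panel) stay open as untested.

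Of 12 neuronal transcripts 5 rose with age in radial precursors and 7 did not pass the edgeR test (camera adjusted p = 2.48e-05, or 0.329 with an estimated correlation). Free neuronal RNA stays open: erythroid cells and microglia at E17.5 held 0.460 times (0.401 to 0.525) the neuronal UMIs per cell of radial precursors, and the interval spans the bound of 0.5 set in advance. Neurons or doublets inside the class would raise every abundant neuronal transcript by a like share of its level in neurons. The bound was set from 15.1%, the median share of the 5 called genes, and 3 of 11 genes stayed below it. This met the limit set in advance, but genes chosen for rising set the bound, so this stays open. Tubb3 and Map1b also stood at 333 and 671 CPM at E11.5, where a fall of their own would hide a share. Changes as such shares ran from -4.46% for Map1b to 37.0% for Rtn1, and a change with age stays open as untested.

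Of 13 stress and immediate early genes 3 rose with age in radial precursors and 10 did not pass the edgeR test (camera adjusted p = 4.98e-05, or 0.329 with an estimated correlation). Handling that acted on every cell of a library stays open, since the classes differed. Mean slopes were 0.366 log2 per day in radial precursors, 0.26 in ganglionic eminence precursors, 0.199 in intermediate progenitors, 0.105 in inhibitory neurons and -0.0674 (SE 0.0414) in excitatory neurons. Viability sorting, which only E11.5 lacked, stays open: over the 3 sorted libraries the mean slope was 0.203 (SE 0.117). Age stays open as untested.

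The 12 orderings of the 4 libraries are too few for a share under 0.05. In radial precursors the real order gave 313 called genes and the highest of the others 1, so 1 of the 12 orderings gave as many. For intermediate progenitors the values were 531 and 0, again 1 of 12.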

How the results depend on the processing

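Results named here as moved left the interval or the factor of 1.5 around the reported value, and the cause was not tested except where the setting itself removes genes, libraries or counts, as a filter, a thinning or a left-out library does. Chosen after the data were seen were the cortical tables clustered alone, cells of at least 1000 UMIs, doublets removed, cells without an oligodendrocyte precursor UMI, low-cycle cells, the slopes against other classes, the leaving out of clusters that failed the first marker check and every setting with the E15.5 table split at column 3000. Not run were the non-cycling and the low-cycle cells, which left 2 libraries. The stretches of the split table were not matched to the labelled batches. No paired analysis was possible because each age had 1 library and the replicate numbers pair nothing. Of 1186 values of the 63 called named genes of radial precursors under the alternatives, 1038 stayed past the threshold, 148 did not and 0 reversed, and 22 genes passed in every alternative that tested them (43 of the 63 were tested in all 20, and 14 of these passed in all). In intermediate progenitors the values were 1173 for 65 genes, with 1088 past it, 85 not, 0 reversed and 37 genes past it in every one that tested them (44 were tested in all 19, 19 passed in all). Depth limited the E17.5 radial precursors most, with 166429 UMIs in 72 cells.

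The reported counts were 216 rising and 97 falling genes in radial precursors, 273 and 258 in intermediate progenitors and 0 and 0 in excitatory neurons, the last with 1527 at an unadjusted p under 0.05 by edgeR. Without a low-count filter, 676 genes rose and 540 fell in radial precursors, 672 genes rose and 583 fell in intermediate progenitors and 64 genes rose and 130 fell in excitatory neurons. With a filter of 30 UMIs, 90 genes rose and 20 fell in radial precursors and 140 genes fell in intermediate progenitors. With libraries thinned to the shallowest, 101 genes rose and 19 fell in radial precursors and 1 gene fell in excitatory neurons. At Leiden resolution 2, 131 genes rose and 33 fell in radial precursors and 2 genes rose and 1 fell in excitatory neurons. At Leiden resolution 0.5, 393 genes fell in intermediate progenitors and 3 genes rose and 6 fell in excitatory neurons. With the cortical tables clustered alone, 45 genes fell in radial precursors and 2 genes rose in excitatory neurons. By the DESeq2 Wald test, 79 genes rose and 110 fell in excitatory neurons. Without the clusters that failed the first marker check, 2 genes rose and 4 fell in excitatory neurons. With the E15.5 table as 2 libraries, 366 genes rose and 255 fell in radial precursors and 30 genes rose and 66 fell in excitatory neurons. Without its first stretch, 177 genes rose in intermediate progenitors. Without its second stretch, 143 genes rose in radial precursors. By E17.5 against E11.5 with the spread between the stretches only, 727 genes rose and 698 fell in radial precursors, 1087 genes rose and 1027 fell in intermediate progenitors and 1536 genes rose and 1257 fell in excitatory neurons. Leaving out 1 library at a time, 39 to 617 rose and 6 to 494 fell in radial precursors, 67 to 663 rose and 103 to 466 fell in intermediate progenitors and 0 to 218 rose and 0 to 131 fell in excitatory neurons.

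With an estimated correlation no list that passed camera with the preset correlation stayed past the threshold, and the adjusted p is given here by class. In radial precursors it was 0.329 except 0.407 for cholesterol genes. In intermediate progenitors it was 0.508 except 0.527 for S phase genes and synaptic genes and 0.546 for neuronal transcripts and precursor transcripts. In excitatory neurons it was 0.428 except 0.473 for S phase genes, interneuron transcripts and precursor transcripts, 0.493 for G2/M phase genes, 0.552 for Notch genes and 0.555 for patterning factors and synaptic genes.

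With libraries thinned to the shallowest the camera adjusted p in radial precursors was glycolysis genes 0.212, ligands 0.0758 and upper-layer genes 0.893 (no longer past the threshold) and patterning factors 0.734 (of the other direction). In intermediate progenitors it was growth factor receptors 0.916 (of the other direction). In excitatory neurons it was Notch genes 0.0969 and patterning factors 0.593 (no longer past the threshold), Wnt genes 0.0343 and stress genes 0.0472 (now past it) and cholesterol genes 0.799 and ligands 0.593 (of the other direction). At Leiden resolution 2 the camera adjusted p in intermediate progenitors was stress genes 0.0110 (now past it) and deep-layer genes 0.961 and ribosomal proteins 0.961 (of the other direction). In excitatory neurons it was patterning factors 0.0510, ribosomal proteins 0.345, imprinted genes 0.0582 and precursor transcripts 0.0682 (no longer past the threshold) and ligands 0.939 (of the other direction). At Leiden resolution 0.5 the camera adjusted p in intermediate progenitors was interneuron transcripts 0.0189 (now past it) and astroglial genes 0.843, ligands 0.843 and mitochondrial genes 0.906 (of the other direction). With the cortical tables clustered alone the camera adjusted p in radial precursors was growth factor receptors 0.0811 (no longer past the threshold). In intermediate progenitors it was precursor transcripts 0.0645 (no longer past the threshold), stress genes 0.0163 (now past it) and BMP and Id genes 0.918, patterning factors 0.883, deep-layer genes 0.883 and ribosomal proteins 0.857 (of the other direction). In excitatory neurons it was patterning factors 0.0529, ribosomal proteins 0.0770 and precursor transcripts 0.0770 (no longer past the threshold) and ligands 0.881 (of the other direction). Without the clusters that failed the first marker check the camera adjusted p in excitatory neurons was ribosomal proteins 0.311 (no longer past the threshold) and glycolysis genes 0.853, cholesterol genes 0.903 and ligands 0.888 (of the other direction). With cells of at least 1000 UMIs the camera adjusted p in radial precursors was glycolysis genes 0.0727 and growth factor receptors 0.0533 (no longer past the threshold). With cells of the all-cell tables the camera adjusted p in radial precursors was growth factor receptors 0.0860 (no longer past the threshold) and imprinted genes 0.948 (of the other direction). In intermediate progenitors it was stress genes 0.0455 (now past it) and astroglial genes 0.962 and mitochondrial genes 0.962 (of the other direction). In excitatory neurons it was precursor transcripts 0.0545 (no longer past the threshold) and ligands 0.850 (of the other direction). Without cells with an oligodendrocyte precursor UMI the camera adjusted p in radial precursors was growth factor receptors 0.219 (no longer past the threshold) and ribosomal proteins 0.0416 (now past it). With DESeq2 size factors the camera adjusted p in intermediate progenitors was mitochondrial genes 0.997 (of the other direction). With doublets removed the camera adjusted p in intermediate progenitors was mitochondrial genes 0.978 (of the other direction). In excitatory neurons it was patterning factors 0.104 (no longer past the threshold). With the E15.5 table as 2 libraries the camera adjusted p in radial precursors was Wnt genes 0.915 (of the other direction). In intermediate progenitors it was mitochondrial genes 0.941 (of the other direction).

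With 1 library left out, the camera adjusted p in radial precursors ranged as Wnt genes 0.523 to 0.995, BMP and Id genes 0.00995 to 0.139, patterning factors 0.0584 to 0.925, glycolysis genes 0.00125 to 0.706, cholesterol genes 4.23e-05 to 0.792 and growth factor receptors 0.0411 to 0.117. The other ranges were ligands 0.0399 to 0.112, deep-layer genes 0.0249 to 0.879, upper-layer genes 0.00995 to 0.201, ribosomal proteins 0.00995 to 0.607 and imprinted genes 0.444 to 0.925. Those in intermediate progenitors were astroglial genes 0.154 to 0.972, patterning factors 0.171 to 0.972, cholesterol genes 0.130 to 0.972, growth factor receptors 0.167 to 0.988 and ligands 0.403 to 0.972. The other ranges were stress genes 0.00119 to 0.433, mitochondrial genes 0.251 to 0.972, ribosomal proteins 0.288 to 0.972, imprinted genes 0.0429 to 0.827 and interneuron transcripts 0.0328 to 0.0544. Those in excitatory neurons were S phase genes 1.82e-06 to 0.0764, Notch genes 0.000143 to 0.358, Wnt genes 0.00891 to 0.531, BMP and Id genes 0.662 to 0.937, patterning factors 0.000240 to 0.981, cholesterol genes 0.0355 to 0.937 and growth factor receptors 0.382 to 0.786. The other ranges were ligands 0.503 to 0.932, deep-layer genes 0.00130 to 0.478, synaptic genes 0.000585 to 0.181, stress genes 0.0273 to 0.932, neuronal transcripts 0.382 to 0.981, interneuron transcripts 0.00112 to 0.923 and precursor transcripts 0.0136 to 0.181.

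At Leiden resolution 0.5, the radial precursor share was 65.4% at E11.5, the intermediate progenitor share was 22.5% at E13.5 and 33.2% at E15.5, the excitatory neuron share was 57.6% at E13.5 and 64.1% at E17.5 and the unnamed share was 0% at E11.5, 0% at E13.5, 0.981% at E15.5 and 0% at E17.5. At Leiden resolution 2, the radial precursor share was 33.9% at E11.5, the intermediate progenitor share was 22.0% at E13.5, 16.5% at E15.5 and 18.9% at E17.5, the excitatory neuron share was 17.3% at E11.5 and 47.0% at E17.5 and the unnamed share was 37.3% at E11.5, 15.02% at E13.5 and 22.5% at E17.5. With the cortical tables clustered alone, the radial precursor share was 50.1% at E11.5 and 10.8% at E15.5, the intermediate progenitor share was 12.2% at E17.5, the excitatory neuron share was 51.7% at E15.5 and the unnamed share was 15.4% at E11.5, 18.2% at E13.5, 23.9% at E15.5 and 18.5% at E17.5. With cells of at least 1000 UMIs, the unnamed share was 2.12% at E17.5. The E17.5 over E11.5 ratio of radial precursors carrying list UMIs was 0.468 for G2/M phase and 0.596 for S phase with 1 list UMI, 0.2999 for S phase with 3 list UMIs and 0.570 for S phase without thinning. The ratio of excitatory neurons was 0.317 for G2/M phase and 0.658 for S phase with 1 list UMI, 0.0282 for G2/M phase and 0.202 for S phase with 3 list UMIs and 0.210 for G2/M phase and 0.692 for S phase without thinning. Over genes of at least 10 CPM, Pearson r was 0.855 for E11.5 and E13.5, 0.834 for E11.5 and E15.5, 0.723 for E11.5 and E17.5 and 0.782 for E13.5 and E17.5. Over genes of at least 200 CPM, Pearson r was 0.756 for E11.5 and E13.5, 0.715 for E11.5 and E15.5, 0.472 for E11.5 and E17.5, 0.864 for E13.5 and E15.5 and 0.647 for E13.5 and E17.5.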

Other observations

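The trends in inhibitory neurons and in ganglionic eminence precursors of the all-cell tables were chosen for testing only after the data were seen. In inhibitory neurons 9 genes rose and 32 fell of 8942 by the edgeR trend test (Benjamini-Hochberg adjusted, 4 libraries, 1412 at an unadjusted p under 0.05). Nfix (0.76, SE 0.09, adjusted p = 0.0279), a transcription factor of maturation, rose from 3.69 to 274 CPM, beside Akap7 (0.53, adjusted p = 0.0406) and Cplx2 (0.39, adjusted p = 0.0319). Crabp2 (-1.51, SE 0.11, adjusted p = 0.00280) fell from 905 to 4.51, beside Nefm (-0.56, adjusted p = 0.0214), a neurofilament, Pou3f1 (-0.56, adjusted p = 0.0319), Igf2bp1 (-0.56, adjusted p = 0.0319) and the dividing-cell gene Mki67 (-0.71, adjusted p = 0.0214). Among G2/M genes 0 rose and 5 fell of 17 (0 rising and 13 falling adjusted within the list), among early neuroepithelial genes 0 rose and 2 fell of 10 (0 rising and 7 falling adjusted within the list), and among synaptic and axonal genes 0 rose and 1 fell of 33 (12 rising and 4 falling adjusted within the list). Leaving out 1 library gave 29 to 154 rising and 48 to 180 falling genes.

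In ganglionic eminence precursors 13 genes rose and 11 fell of 6619 by the edgeR trend test (Benjamini-Hochberg adjusted, 624 at an unadjusted p under 0.05). Nfix rose here too (0.65 log2 per day, adjusted p = 0.0232), with Egr1 (0.52, adjusted p = 0.0265), Nr2f1 (0.45, adjusted p = 0.0438), Gria2 (0.40, adjusted p = 0.0147) and Thra (0.32, adjusted p = 0.0438), the thyroid hormone receptor. Crabp2 (-1.25, adjusted p = 3.49e-05), Cdkn1c (-0.66, adjusted p = 0.00863), Ccnd1 (-0.45, adjusted p = 0.00480), Igf2bp1 (-0.42, adjusted p = 0.00863) and Lmo1 (-0.39, adjusted p = 0.00863) were among those that fell. Among G2/M genes 0 rose and 0 fell of 26 (0 rising and 0 falling adjusted within the list), in a class of dividing cells, among early neuroepithelial genes 0 rose and 5 fell of 11 (0 rising and 5 falling adjusted within the list) and among astroglial genes 1 rose and 0 fell of 16 (6 rising and 0 falling adjusted within the list). Leaving out 1 library gave from 31 rising genes to 11.9 times the reported 13, the most without E13.5, and 21 to 77 falling genes.

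In the E15.5 all-cell table, blocks of 500 columns from column 1 to 3000 held 2314 to 3811 CPM of mt-Rnr2 and 2909 to 3921 of Malat1. Blocks from column 3001 to 5000 held 8709 to 13321 of mt-Rnr2 and 7114 to 11240.3 of Malat1.

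The E11.5 radial precursors included a cluster of 208 cortical cells with a median of 894 UMIs per cell, counted over all 275 of its cells. At E15.5 they included a cluster of 18 cortical cells led by Wnt8b and Rspo2.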
